A study of Homo sapiens with 24 samples.

How the data were processed

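The authors deposited per-gene counts for each library in the layout of STAR gene counts, with 3 count columns: unstranded and one for each strand. The submitters' processing notes name STAR, HTSeq and DESeq2 with hg38 and give no versions. The deposited counts hold 58721 gene IDs, all of which match GENCODE 29 on GRCh38, whose symbols and coordinates were used. The unstranded column was analysed because reads fell evenly on both strands. Of total reads, 71.0% to 80.5% were assigned to genes, 1.34% to 5.44% were unmapped, 2.11% to 3.44% mapped to several places, 4.60% to 11.1% met no gene and 9.49% to 11.1% met more than one gene. Totals ran from 21249722 to 37455958 reads per library, and gene counts from 16774179 to 30159260 in LN-229 and from 16223239 to 24272308 in DKO cells. The counts of ZNF593 come from both stranded columns summed, and no gene-level result rests on that sum apart from those given for it.

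Each cell line was fitted alone with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, with 1 coefficient per group, TMM factors (0.952 to 1.05 in LN-229, 0.978 to 1.02 in DKO cells) and genes kept by filterByExpr. The biological coefficient of variation was 11.2% in LN-229 and 5.26% in DKO cells. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over all tested genes of a comparison. The SE is the absolute log2 change over the square root of F. CPM are means ± SD of 3 libraries over TMM-scaled totals, except those of ZFX, ZNF711 and ZNF593 as targets, which are over plain totals. Gene lists, 33 in number, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over lists; camera sets a list against the other genes and fry against no change. Counts called "over all genes" use the adjustment over all genes, and those "adjusted over the list alone" adjust the members' p-values within the list. Lists were written from general knowledge of gene function, so they are not complete. Overlaps used Fisher's exact test with the product of the set sizes over the shared genes as the count due by chance, and 20 simulations of no effect gave the correlation from shared controls. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the data, ran the motif test and drew the figures.

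Genes are named by a rule. For each of 6 comparisons the targeted factors were named, with the 10 protein-coding genes of largest rise and the 10 of largest fall among those called, at a mean of at least 5 CPM over the groups compared and no overlap of CPM between them. Up to 4 members of each list with the largest absolute change were also named. Genes used to read sex and genes without a symbol were left out. The text describes part of these genes, and the other values are kept with the results; single values of a pair of list members are not reported here, nor counted among the alternatives, though their lists keep them. For genes of the comparisons without own named genes, values are those of genes named elsewhere.

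A self-test planted changes in counts drawn from the fitted model. It recovered 47.7%, 71.2% and 90.6% of genes changed 1.5-, 2- and 4-fold for siZFX, 64.6%, 84.8% and 97.0% for wtZFX, 16.4%, 53.1% and 84.6% for the difference between the double knockdown and siZFX, and 3.03%, 35.9% and 60.9% for the difference from the sum. The stop rule written at the start asked for 80% at 4-fold. It was replaced after the last of these was seen to fall short, and that comparison missed most planted changes of 1.5- and 2-fold. The self-test planted 200 changed genes, and recovery can differ where another number of genes changes. False calls were 5, 14, 4 and 1, of 17212, 19047, 17183 and 17179 genes fitted, and 0 of 40 random lists were called.

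The groups, comparisons, tests, gene lists, rule for named genes and the alternatives not described as added were chosen before the data were examined. The alternatives tried were RLE and upper-quartile factors, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, only the groups of the contrast in the fit, a replicate block, the larger stranded column, GC and length offsets, leaving out each library, siControl or all 6 controls in place of siControl_2, and calls of at least 1.5-fold. Both stranded columns summed, the double library that lay apart left out, the motif test, and siControl in place of siControl_2 for list medians and for single genes of the differences were added later. DESeq2 entries without a value stay without one. For overlaps and gene lists, a replicate left out was taken out of every group of the cell line at once. A planned search for the ZFX motif in promoters was not run because no genome sequence was at hand; ChIP data of the series were not analysed here.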

Results

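Gene expression was measured by RNA-seq in 2 human cell lines, in 24 libraries that fall into 8 groups of 3 replicates. LN-229, an established glioblastoma line, gave 15 libraries in 5 groups. Its cells received a control siRNA (siControl), an siRNA against ZFX (siZFX), an siRNA against ZNF593 (siZNF593), both of these siRNAs together (the double knockdown), or control siRNA in a further set (siControl_2). Both control sets carry the same treatment label, and only the names of the deposited data mark siControl_2 as the control of the double knockdown. The other 9 libraries came from 293T cells, a line derived from human embryonic kidney, in which ZFX and ZNF711 had been knocked out (DKO cells). DKO cells received the empty pCMV6 vector, FLAG-tagged wild-type ZFX (wtZFX) or a ZFX construct named ZFX12_13, whose meaning the labels do not state. ZFX is a zinc finger transcription activator encoded on the X chromosome, ZNF711 is its close paralog, and ZNF593 is another zinc finger protein. The libraries held 16223239 to 30159260 reads counted on genes, and 17684 genes in LN-229 and 19376 in DKO cells had enough counts to be tested. The series calls the 3 libraries of each group biological replicates without saying that they came from separate cultures, so p-values here measure the spread between these samples, which may be technical.

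Between replicates of a group, Pearson correlations of log CPM across genes ran from 0.982 to 0.997 over 24 pairs. The lowest was that of replicates 1 and 3 of the double knockdown. In LN-229 the first principal component held 22.3% of the variance and the second 21.6%, and replicate 3 of the double knockdown lay apart from replicates 1 and 2 of its group (first component -78.5 against -33.0 and -34.2). In DKO cells the first component held 48.9% and set the empty vector (-47.9 to -49.9) apart from wtZFX (25.3 to 26.7) and ZFX12_13 (22.1 to 24.9). The second component, with 19.7%, set wtZFX (24.8 to 27.3) apart from ZFX12_13 (-25.1 to -31.0).

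**Figure D1:**
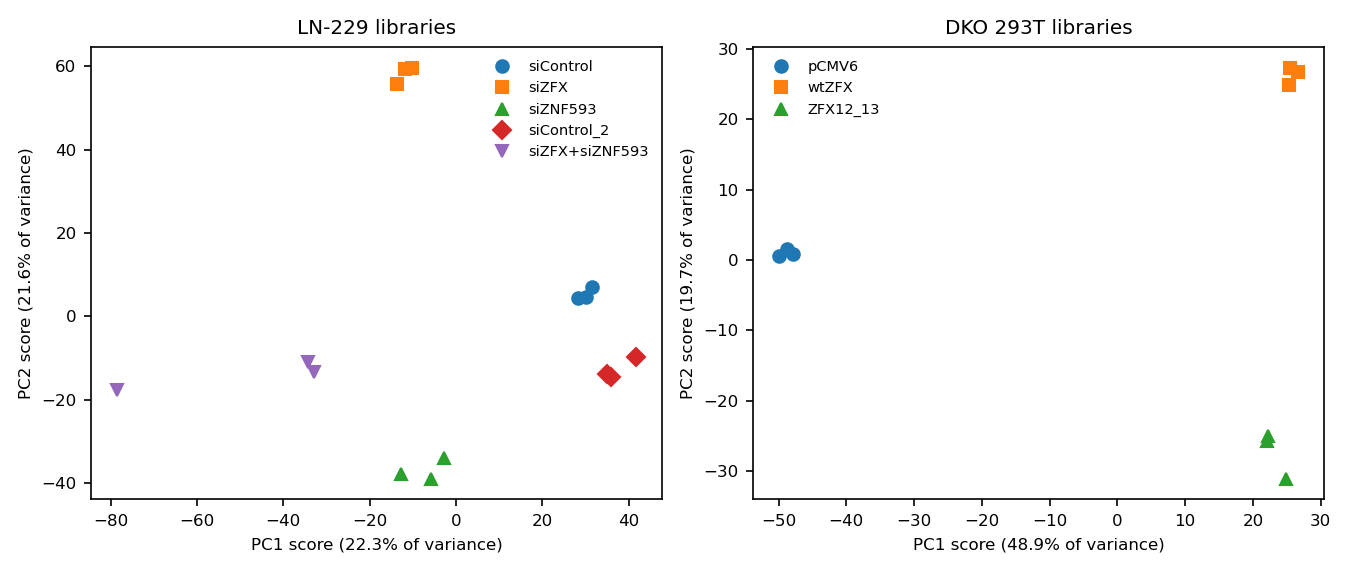
Each point is 1 library, placed by its first and second principal component of log2 CPM, with colours for groups and a panel for each cell line. The first component holds 22.3% of the variance in LN-229 and 48.9% in DKO cells.

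ZFX transcripts fell from 49.6 ± 4.22 CPM in siControl to 15.7 ± 3.58 CPM with siZFX (mean ± SD, n = 3), which left 31.7% of control (log2 change -1.66, SE 0.13, adjusted p = 1.1e-09). The double knockdown lowered ZFX less, to 27.5 ± 2.48 CPM from 52.0 ± 4.89 CPM in siControl_2 (49.8% left; log2 change -1.01, SE 0.12, adjusted p = 9.5e-07). These log2 changes differ by 0.65 (SE 0.17, adjusted p = 0.0112). With siZNF593 alone ZFX was unchanged at 56.5 ± 4.45 CPM (adjusted p = 0.545). ZNF593 had 0 counts in the unstranded column because its whole span lies under AL391650.1 on the opposite strand. Summed over both stranded columns, reads at ZNF593 fell from 29.4 ± 2.14 to 2.03 ± 0.592 CPM with siZNF593 (log2 change -3.93, SE 0.17, adjusted p = 8.3e-14) and from 30.1 ± 2.72 to 2.78 ± 0.405 CPM with the double knockdown (log2 change -3.50, SE 0.15, adjusted p = 2.6e-13). That sum cannot separate ZNF593 from AL391650.1. In DKO cells ZFX rose from 227 ± 10.8 CPM with the empty vector to 15430.1 ± 1202 CPM with wtZFX (log2 change 6.12, SE 0.14, adjusted p = 7.3e-10) and 18637 ± 3034 CPM with ZFX12_13, whose levels did not differ (log2 0.28, SE 0.11, adjusted p = 0.123). Reads from the introduced constructs are counted on ZFX. The empty-vector cells kept reads on ZFX and ZNF711 (310.2 ± 5.36 CPM); gene counts do not show the edits, and parental 293T cells were not analysed here.

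**Figure D2:**
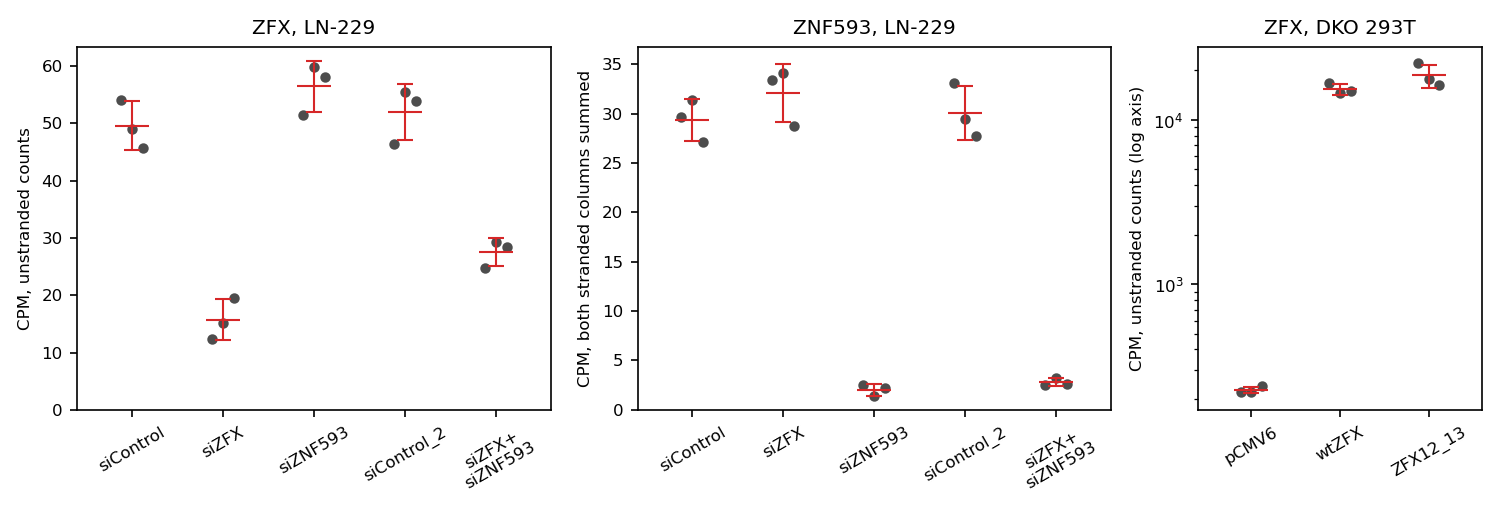
Dots are libraries and red bars mean ± SD of CPM for ZFX in LN-229, ZNF593 in LN-229 (both stranded columns summed) and ZFX in DKO cells (log axis). ZFX fell to 31.7% of control with siZFX and to 49.8% with the double knockdown.

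The comparison of siZFX with siControl asked which transcripts changed in LN-229 when ZFX was lowered. HMOX1 (ENSG00000100292.16, chromosome 22, 35380361 to 35394214), which encodes the heme-degrading enzyme heme oxygenase 1, rose 4.97-fold, from 21.4 ± 0.988 to 106 ± 6.66 CPM (log2 change 2.31, SE 0.12, adjusted p = 1.3e-12, n = 3). BMF, a pro-apoptotic BCL2 family member, rose 5.04-fold to 21.2 ± 1.23 CPM (log2 2.33, SE 0.14), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 3.45-fold to 19.1 ± 2.77 CPM (log2 1.79, SE 0.20). DPYSL4 (ENSG00000151640.12, chromosome 10, 132186900 to 132205776), of the collapsin response mediator family, fell from 39.4 ± 2.33 to 5.82 ± 0.302 CPM (log2 change -2.76, SE 0.15, adjusted p = 2.6e-12). SMO, the Hedgehog signal transducer, fell from 36.5 ± 1.46 to 5.68 ± 0.900 CPM (log2 -2.69, SE 0.13), and the Golgi mannosidase gene MAN2A2 from 73.9 ± 2.99 to 9.20 ± 0.502 CPM (log2 -3.01, SE 0.10, adjusted p = 2.8e-15). The largest fold among the 10 leading falls was 11.0, at BAHCC1, and the smallest 6.43; the 10 leading rises ran from 3.27-fold to 5.04-fold. Of these 20 genes 15 share part of their span with another gene, among them BMF, ANGPTL4, SMO, MAN2A2 and BAHCC1, and their values are uncertain because the counts are unstranded.

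Of 33 gene lists 8 passed the camera test with siZFX, 4 in each direction, and 5 did without replicate 1. For lists and overlaps, a replicate number left out here and below was taken out of every group of the cell line. With an estimated correlation between genes 0 passed. That setting gave the highest adjusted p of every alternative for each list called in this text. DNA replication genes fell (median log2 change -0.35, adjusted p = 1.4e-07; adjusted p = 0.0954 with an estimated correlation), 28 of 39 being lower in the test over all genes and 30 when adjusted over the list alone. In that list CCNE1, the cyclin of S-phase entry, fell from 12.7 ± 1.12 to 5.05 ± 1.02 CPM (log2 -1.33, SE 0.20), and CHAF1B, a chromatin assembly factor subunit, from 21.5 ± 1.13 to 9.85 ± 0.745 CPM. Oligodendrocyte genes fell too (median -0.88, adjusted p = 2.0e-05; adjusted p = 0.0954 with an estimated correlation), with 8 of 9 lower over all genes and 8 adjusted over the list alone. CSPG4, a proteoglycan of glial progenitors, went from 300.8 ± 7.51 to 72.0 ± 1.48 CPM (log2 -2.06, SE 0.15, adjusted p = 8.3e-08), and SOX10, a glial transcription factor, from 1276 ± 16.9 to 683 ± 34.8 CPM. G2/M genes fell (median -0.22, adjusted p = 2.0e-05; adjusted p = 0.485 with an estimated correlation), with 22 of 44 lower over all genes and 24 adjusted over the list alone, and the proliferation marker MKI67 went from 554 ± 34.3 to 379 ± 12.4 CPM. Mitochondrially encoded mRNAs rose (median 0.47, adjusted p = 0.00146; adjusted p = 0.511 with an estimated correlation), with 6 of 13 higher over all genes and 9 adjusted over the list alone; MT-ATP6 rose by a log2 of 0.58. Mitochondrial reads made up 4.45% to 4.60% of counts with siZFX and 3.19% to 3.60% in siControl, but 4.32% to 5.01% in siControl_2. The list of TIP60 complex genes, which include a histone H4 acetyltransferase, did not pass (median 0.11, adjusted p = 0.175), nor did MSL, NSL and HBO1 acetyltransferase genes (median 0.04, adjusted p = 0.523) or Pol II pausing factors (median 0.12, adjusted p = 0.153). The fry test, which asks whether a list changed at all and not whether it changed more than other genes, gave adjusted p = 0.00184 for the TIP60 list and 0.00481 for the pausing factors. In all, 2439 genes were higher and 3025 lower with siZFX, 839 and 1603 of them by at least 1.5-fold; with only these groups in the fit 3775 were higher, and with GC and length offsets the majority turned, to 3704 higher and 3088 lower.

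The comparison of siZNF593 with siControl asked which transcripts changed in LN-229 when ZNF593 was lowered. TFRC (ENSG00000072274.12, chromosome 3, 196027183 to 196082189), the transferrin receptor gene, fell from 407 ± 11.0 to 57.0 ± 4.09 CPM (log2 change -2.84, SE 0.08, adjusted p = 6.0e-17, n = 3). CXCL1, a neutrophil-attracting chemokine, fell from 43.5 ± 2.90 to 3.90 ± 0.821 CPM (log2 -3.47, SE 0.22, adjusted p = 1.2e-08), and IGFBP3, a binding protein of insulin-like growth factors, from 46.7 ± 2.81 to 7.76 ± 0.887 CPM (log2 -2.59, SE 0.12). ETV5, an ETS factor downstream of ERK signalling, fell from 104 ± 0.614 to 16.3 ± 1.18 CPM (log2 -2.68, SE 0.07). Among rises, the matricellular protein gene CCN3 went from 17.7 ± 0.489 to 83.7 ± 5.49 CPM (log2 2.24, SE 0.10, adjusted p = 8.7e-14), and ACAN, which encodes the cartilage proteoglycan aggrecan, from 6.501 ± 0.331 to 22.8 ± 1.96 CPM (log2 1.81, SE 0.15). TFRC, ETV5 and CCN3 are among the 12 of 20 leading genes that overlap another gene.

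With siZNF593, 15 of 33 lists passed and 14 of them fell. DNA replication genes fell (median -0.55, adjusted p = 1.3e-18; adjusted p = 0.00906 with an estimated correlation), with 32 of 39 lower over all genes and 34 adjusted over the list alone; the helicase subunit gene MCM7 went from 486 ± 4.83 to 224 ± 9.17 CPM (log2 -1.12, SE 0.07). Histone deacetylase complex genes fell (median -0.18, adjusted p = 0.0016; adjusted p = 0.0437 with an estimated correlation), with 12 of 28 lower over all genes and 12 adjusted over the list alone, and HDAC3 went from 60.8 ± 5.08 to 39.5 ± 2.63 CPM. The other lists did not pass with an estimated correlation. G2/M genes fell (median -0.35, adjusted p = 7.3e-13; adjusted p = 0.0847 with an estimated correlation), with 30 of 44 lower over all genes and 35 adjusted over the list alone, and the survivin gene BIRC5 went from 336 ± 19.96 to 166 ± 7.36 CPM. Immediate early and growth factor response genes fell (median -0.47, adjusted p = 4.0e-07; adjusted p = 0.172 with an estimated correlation), with 17 of 28 lower over all genes and 20 adjusted over the list alone, and the ERK pathway inhibitor gene SPRY4 went from 152 ± 8.13 to 51.5 ± 0.754 CPM. LN-229 marker genes fell (median -0.21, adjusted p = 0.0016; adjusted p = 0.147 with an estimated correlation), with 8 of 16 lower over all genes and 9 adjusted over the list alone. Among them the receptor kinase gene AXL fell from 705 ± 16.7 to 149 ± 16.5 CPM (log2 -2.25, SE 0.08, adjusted p = 4.1e-15). Ribosomal protein genes were the list that rose (median 0.12, adjusted p = 0.00215; adjusted p = 0.638 with an estimated correlation), 15 of 77 being higher over all genes and 14 adjusted over the list alone. In all, 2164 genes were higher and 2577 lower; GC and length offsets gave 1994 and 4130, which moved the share of higher genes from 45.6% to 32.6%, and upper-quartile factors turned the majority (2648 and 2138).

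Setting siZFX against siZNF593 directly asked which transcripts told these knockdowns apart. ANGPTL4 was 17.6-fold higher with siZFX (log2 difference 4.14, SE 0.24, adjusted p = 4.4e-12), as it rose with siZFX and fell with siZNF593 (log2 -2.35, SE 0.25). HMOX1 was 8.38-fold higher with siZFX (log2 3.07, SE 0.13, adjusted p = 1.1e-14), and TFRC, unchanged by siZFX (log2 0.18, adjusted p = 0.077), was higher by a log2 of 3.01 (SE 0.08). ACAN lay 11.0-fold lower with siZFX (log2 -3.46, SE 0.18, adjusted p = 4.5e-13), and the secreted protease inhibitor gene PI15 26.5-fold lower (log2 -4.73, SE 0.26). By camera 18 of 33 lists passed, 17 of them higher with siZFX and 1 lower, and 0 passed with an estimated correlation. Histone deacetylase complex genes were higher with siZFX (median 0.24, adjusted p = 0.00357, and adjusted p = 0.116 with an estimated correlation), with 13 of 28 higher over all genes and 16 adjusted over the list alone. Pol II pausing factors were higher as well (median 0.37, adjusted p = 0.0122; adjusted p = 0.144 with an estimated correlation), with 12 of 25 over all genes and 13 adjusted over the list alone. In all, 3504 genes were higher and 3660 lower with siZFX than with siZNF593, 40.5% of those tested; GC and length offsets gave 5520 and 3148, moved the share of higher genes from 48.9% to 63.7% and shifted the median of all genes by 0.12.

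Against the same siControl libraries, 549 genes rose with both knockdowns where 298 were due by chance, and 796 fell with both where 441 were due. BMF and PGM2L1 were among the shared rises, with log2 changes of 1.17 and 1.46 with siZNF593, and CXCL1 and CXCL8 among the shared falls, with -1.78 and -1.36 with siZFX. With replicate 1 taken out of every group the shared counts were 272 and 392, and with replicate 2 taken out of every group they were 178 and 327. Opposite changes numbered 429 (fall with siZFX, rise with siZNF593; 370.2 due by chance) and 397 (rise with siZFX, fall with siZNF593; 355 due). Across genes, which are not independent replicates, the changes correlated at r = 0.17 (Spearman 0.17); 20 simulations of no effect with shared controls gave r = 0.478. The covariance was 0.0698 against a simulated 0.0417, at most 0.0461, and the simulations called 0 genes with both in either direction. Simulations of no effect cannot tell how much shared controls add where effects exist. Part of the shared excess may therefore come from the shared controls.

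The double knockdown was compared with siControl_2 to ask what changed when both factors were lowered. CXCL1 (ENSG00000163739.4, chromosome 4, 73869393 to 73871242) fell 40.5-fold, from 141 ± 10.9 to 3.48 ± 1.60 CPM (log2 change -5.34, SE 0.22, adjusted p = 9.5e-11, n = 3). CXCL8, the interleukin 8 gene, fell from 109 ± 6.64 to 5.12 ± 1.70 CPM (log2 -4.41, SE 0.16), and TNFAIP2, a gene induced by tumour necrosis factor, from 11.6 ± 1.57 to 0.685 ± 0.184 CPM (log2 -4.07, SE 0.24). BAHCC1 fell 26.7-fold (log2 -4.74, SE 0.24). OASL, an interferon-induced gene, rose from 1.51 ± 0.668 to 11.6 ± 1.49 CPM (log2 2.95, SE 0.25, adjusted p = 3.7e-09), and PGM2L1, a sugar bisphosphate synthase gene, from 19.1 ± 0.813 to 87.4 ± 13.8 CPM (log2 2.20, SE 0.10). Against siControl the log2 changes were -3.64 for CXCL1 (12.5-fold), -2.77 for CXCL8, -2.76 for TNFAIP2, -4.15 for BAHCC1 and 2.33 for OASL. CALB2 rose (log2 1.71) and C3 fell (log2 -2.63) against siControl_2, but against siControl their changes were -1.21 and 0.51. BAHCC1, PGM2L1 and C3 are among the 11 of 20 leading genes that overlap another gene.

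Inflammatory genes fell with the double knockdown (median -1.23, adjusted p = 8.0e-11; adjusted p = 0.0463 with an estimated correlation), with 20 of 24 lower over all genes and 21 adjusted over the list alone; against siControl the median was -0.59, with 13 lower over all genes. The same list was higher in siControl_2 than in siControl (median 0.66, adjusted p = 5.4e-09; adjusted p = 0.0284 with an estimated correlation), 14 of 24 being higher over all genes and 15 adjusted over the list alone. Extracellular matrix genes fell (median -0.23, adjusted p = 0.000373, and adjusted p = 0.23 with an estimated correlation), with 22 of 39 lower over all genes and 23 adjusted over the list alone. Against siControl their median was -0.16, with 15 lower and 10 higher over all genes. COL3A1, a fibrillar collagen gene, went from 7.92 ± 0.627 to 1.03 ± 0.526 CPM (log2 -2.93), a call lost against siControl (log2 -0.40). Heat shock genes fell (median -0.41, adjusted p = 0.00536; adjusted p = 0.293 with an estimated correlation), with 12 of 18 lower over all genes and 12 adjusted over the list alone. DNA replication genes fell (median -0.20, adjusted p = 0.00188; adjusted p = 0.293 with an estimated correlation), 21 of 39 being lower over all genes and 21 adjusted over the list alone, with CCNE1 at a log2 of -1.70; against siControl the median was -0.37, with 26 lower. Cholesterol synthesis genes rose (median 0.17, adjusted p = 0.0374; adjusted p = 0.23 with an estimated correlation; 0.102 without replicate 2), with 11 of 24 higher over all genes and 11 adjusted over the list alone; against siControl the median was 0.42, with 16 higher. HSD17B7 of that list rose from 21.5 ± 0.818 to 44.3 ± 9.15 CPM. In all, 3117 genes were higher and 3636 lower, and upper-quartile factors turned the majority (3805 and 3134). Across genes the changes of the double knockdown fell with GC content (Spearman -0.289), and its list tests were not run with GC and length offsets. Of the 3025 genes lower with siZFX 57.9% were lower with the double knockdown, and of the 2577 lower with siZNF593 56.7% were.

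The control sets were compared to ask how far siControl_2 differed from siControl. CXCL1 was higher in siControl_2 by a log2 of 1.70 (SE 0.18), CXCL8 by 1.64 (SE 0.14) and TNFAIP2 by 1.31. TGF-beta and YAP target genes were lower (median -0.37, adjusted p = 7.5e-09; adjusted p = 0.0199 with an estimated correlation), with 12 of 26 over all genes and 15 adjusted over the list alone. Cholesterol synthesis genes were higher (median 0.24, adjusted p = 3.7e-06; adjusted p = 0.0111 with an estimated correlation), with 11 of 24 over all genes and 11 adjusted over the list alone. In all, 961 genes were higher and 863 lower in siControl_2, 10.3% of those tested; with only these groups in the fit 1831 and 1869 were, and without the filter 956 and 1118. Without replicate 3 of siControl 616 genes were higher, and without replicate 1 or replicate 2 of siControl 564 were lower.

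Each knockdown set against its own control set, the effect of the double knockdown was compared with that of siZFX alone to ask where they differed. The double lowered ZNF593 as well but lowered ZFX less (49.8% left against 31.7%). A difference therefore cannot be put down to ZNF593 alone. HMOX1, raised by siZFX, was not changed by the double knockdown (log2 0.14, adjusted p = 0.401), and the effects differed by -2.18 (SE 0.17, adjusted p = 2.8e-09). CXCL1 fell further with the double knockdown (difference -3.55, or -1.86 with siControl for both), and TFRC, unchanged by siZFX, fell with it (difference -1.78). MAN2A2 fell less with it (log2 -1.40 against -3.01; difference 1.60, SE 0.13, adjusted p = 7.2e-09), and PI15 turned from a fall with siZFX (log2 -2.79) to a rise (log2 1.45). Inflammatory genes had the lower effect (median -1.33, adjusted p = 7.9e-10; adjusted p = 0.064 with an estimated correlation), with 13 of 24 lower over all genes and 17 adjusted over the list alone; with siControl for both the median was -0.66. Oligodendrocyte genes had the higher effect (median 0.63, adjusted p = 0.00132; adjusted p = 0.17 with an estimated correlation), with 6 of 9 over all genes and 7 adjusted over the list alone; with siControl for both the median was 1.33. In all, 1550 effects were higher and 1587 lower. With the same controls for both knockdowns the controls cancel, so values with siControl for both set double libraries against siZFX libraries directly. That direct comparison gave 3006 and 3103 genes, or 2582 and 2710 in a fit with all 6 controls as one group. It keeps any difference that siControl_2 and the double share. Set against their own controls, the effects numbered 1790 and 1407 with upper-quartile factors. GC and length offsets gave 1335 and 2947, moved the share of higher genes from 49.4% to 31.2% and shifted the median of all genes by -0.13.

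The effect of the double knockdown was also compared with the sum of the single effects, to ask where the knockdowns did not add up on the log2 scale. ZFX was lowered less in the double (49.8% left against 31.7% with siZFX), its own log2 change lying 0.54 above the sum (adjusted p = 0.233). Effects smaller than the sum may come from that, which was not tested. TNFAIP2 fell far below the sum (difference -4.30, SE 0.43, adjusted p = 1.5e-06), with log2 changes of 0.08 and 0.15 in the single knockdowns (adjusted p = 0.80 and 0.65) and a level 1.31 higher in siControl_2 than in siControl. BMF rose less than the sum (difference -2.78, SE 0.29, adjusted p = 2.7e-06), and IGFBP3 fell less (difference 2.25, SE 0.22, adjusted p = 1.1e-06). CXCL1 had no difference past the test (-0.08, adjusted p = 0.95), a test that recovered 35.9% of simulated 2-fold changes. With siControl in place of siControl_2, chosen for these genes after the data were examined, the differences were -2.99 for TNFAIP2, -1.96 for BMF and 1.61 for CXCL1. By camera 15 of 33 lists passed, 9 above the sum and 6 below, and 1 passed with an estimated correlation. DNA replication genes lay above the sum (median 0.69, adjusted p = 2.0e-22, and adjusted p = 0.00434 with an estimated correlation), with 24 of 39 over all genes and 33 adjusted over the list alone. With siControl in place of siControl_2 their median was 0.60. By that choice the median of inflammatory genes moved from -0.89 to -0.13, and that of ribosomal protein genes from -0.30 to -0.31. In all, 680 genes were above and 320 below the sum. With siControl in place of siControl_2 these were 1607 and 1056, with all 6 controls 1689 and 1161, and with GC and length offsets 984 and 708, which moved the share above from 68.0% to 58.2%. Without replicate 1 of siControl these were 441 and 165, without its replicate 2 405 and 146, and without replicate 3 of the double knockdown 1334 and 713. Fewer genes were below without replicate 3 of siControl (156), replicate 1 of siZFX (211) or replicate 2 of siZFX (198).

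**Figure D3:**
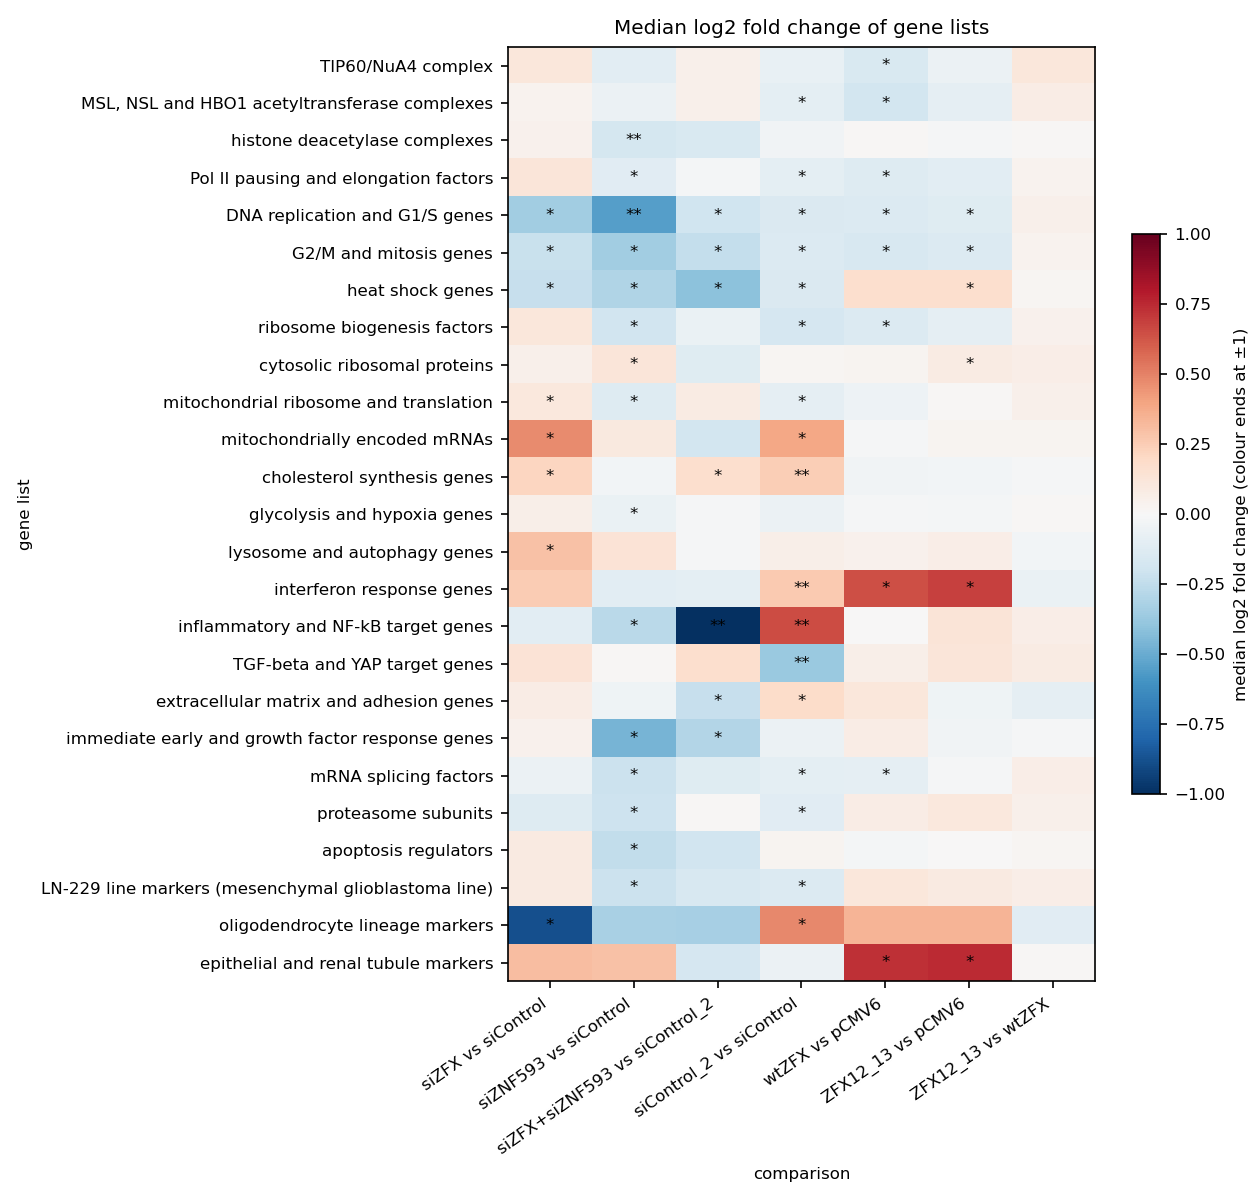
Colour gives the median log2 change of each gene list (rows) in each comparison (columns), ending at 1 in either direction, with 1 star for lists past the camera test and a pair of stars for those also past it with an estimated correlation. Inflammatory genes with the double knockdown (-1.23) and DNA replication genes with siZNF593 (-0.55) carry a pair of stars.

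Adding wtZFX back was compared with the empty vector to ask which transcripts ZFX changed in DKO cells. SUSD2 (ENSG00000099994.10, chromosome 22, 24181259 to 24189110), a membrane protein gene, rose 41.3-fold, from 0.507 ± 0.0735 to 21.1 ± 0.601 CPM (log2 change 5.37, SE 0.15, adjusted p = 7.1e-18, n = 3). WNT7B, a secreted Wnt ligand gene, rose from 1.58 ± 0.428 to 24.4 ± 1.28 CPM (log2 3.96, SE 0.14), and NR5A1, the steroidogenic factor 1 gene, from 0.9504 ± 0.430 to 15.8 ± 0.767 CPM (log2 4.03, SE 0.19). MAP6, a microtubule stabilizing protein gene, rose from 0.271 ± 0.0828 to 11.8 ± 1.72 CPM (log2 5.42, SE 0.21), and the growth factor gene PDGFA from 1.79 ± 0.2997 to 20.7 ± 1.10 CPM (log2 3.53, SE 0.12). Falls were smaller: CSRNP3 went from 27.4 ± 0.416 to 13.8 ± 0.830 CPM (log2 -0.99, SE 0.08, adjusted p = 6.0e-10) and SPINK5, a serine protease inhibitor gene, from 9.99 ± 1.41 to 4.66 ± 0.0976 CPM (log2 -1.10). MAP6 is among the 10 of 20 leading genes that overlap another gene.

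With wtZFX 9 lists passed, 2 of them rising, and 0 did with an estimated correlation; 5 passed without replicate 2. Interferon-induced genes rose (median 0.64, adjusted p = 8.9e-06; adjusted p = 0.693 with an estimated correlation), with 23 of 33 higher over all genes and 23 adjusted over the list alone; IFIT2 went from 1.59 ± 0.369 to 7.14 ± 0.962 CPM (log2 2.16, SE 0.18). Epithelial genes rose (median 0.73, adjusted p = 0.00849; adjusted p = 0.602 with an estimated correlation), with 6 of 7 higher over all genes and 6 adjusted over the list alone, and the keratin gene KRT8 went from 15.6 ± 0.904 to 32.6 ± 2.08 CPM (log2 1.06, SE 0.08). TIP60 complex genes fell (median -0.15, adjusted p = 0.00394; adjusted p = 0.693 with an estimated correlation), with 9 of 18 lower over all genes and 10 adjusted over the list alone, and EPC1 of that complex went from 44.4 ± 0.937 to 29.4 ± 1.08 CPM. MSL, NSL and HBO1 genes fell (median -0.18, 12 of 21 over all genes and 12 adjusted over the list alone), as did pausing factors (median -0.13, 12 of 25 and 12), each at adjusted p = 0.028 and adjusted p = 0.693 with an estimated correlation; without replicate 2 both stood at 0.0699 and without replicate 3 at 0.0546. DNA replication genes fell (median -0.13, adjusted p = 0.0013; adjusted p = 0.875 with an estimated correlation), with 21 of 39 lower over all genes and 24 adjusted over the list alone, while CCNE1 rose from 26.5 ± 0.924 to 40.5 ± 1.74 CPM. In all, 4488 genes were higher and 3714 lower with wtZFX; by at least 2-fold these were 1225 and 120. Among all calls the majority turned with GC and length offsets (4106 higher and 4824 lower) and with upper-quartile factors (4134 and 4356). Across genes the changes rose with GC content (Spearman 0.309, and 0.287 with ZFX12_13), and the list tests were not run with these offsets.

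ZFX12_13 was compared with the empty vector to ask which transcripts this construct changed. MAP6 rose 102-fold to 27.9 ± 1.61 CPM (log2 change 6.67, SE 0.19, adjusted p = 4.6e-18, n = 3). KCNK3, a potassium channel gene, rose from 0.222 ± 0.0325 to 10.1 ± 0.805 CPM (log2 5.48, SE 0.23, adjusted p = 2.5e-15), and IL11, a cytokine gene, from 0.640 ± 0.309 to 17.0 ± 1.40 CPM (log2 4.70, SE 0.19). SOX5, a transcription factor gene, fell from 12.9 ± 0.471 to 7.53 ± 0.383 CPM (log2 -0.78, SE 0.10), and CSRNP3 to 16.1 ± 1.45 CPM (log2 -0.77, SE 0.08). MAP6 and SOX5 are among the 14 of 20 leading genes that overlap another gene. Of 33 lists 6 passed, and 3 did without replicate 3. Interferon-induced genes rose (median 0.69, adjusted p = 1.9e-05; adjusted p = 0.755 with an estimated correlation), with 23 of 33 higher over all genes and 23 adjusted over the list alone, and IFI44 rose by a log2 of 2.44. Epithelial genes rose (median 0.74, adjusted p = 0.0113; adjusted p = 0.544 with an estimated correlation), with 6 of 7 higher over all genes and 6 adjusted over the list alone, and KRT8 reached 49.7 ± 2.93 CPM. Pausing factors did not pass (median -0.11, adjusted p = 0.0548). In all, 4045 genes were higher and 3041 lower; with GC and length offsets the majority turned, to 3816 and 4161.

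ZFX12_13 was then set against wtZFX to ask where the constructs differed. DMTN, an actin-binding protein gene, was 5.64-fold higher with ZFX12_13 (45.3 ± 1.79 against 8.02 ± 0.921 CPM; log2 difference 2.49, SE 0.09, adjusted p = 2.3e-15, n = 3), and the Wnt ligand gene WNT3A 3.45-fold higher (23.7 ± 1.37 against 6.89 ± 1.11 CPM; log2 1.78, SE 0.11). NGFR, a neurotrophin receptor gene, was 3.37-fold lower (5.63 ± 0.633 against 18.9 ± 0.358 CPM; log2 -1.75, SE 0.11, adjusted p = 3.3e-11). Against the empty vector NGFR rose with wtZFX (log2 1.81, SE 0.11) and was unchanged with ZFX12_13 (log2 0.06, SE 0.13, adjusted p = 0.75). MAFA, a transcription factor gene, was 4.12-fold lower (11.0 ± 0.705 against 45.5 ± 0.742 CPM), having risen with each construct (log2 3.01 with wtZFX and 0.96 with ZFX12_13). SUSD2 was lower by a log2 of -1.30 (SE 0.10), and NR5A1 did not differ (log2 0.24, adjusted p = 0.17). By camera 0 of 33 lists passed, with 7 at an unadjusted p under 0.05 (0 with an estimated correlation), while fry, which tests against no change, passed 3; 9 lists passed without replicate 3 and 1 without replicate 2. In all, 1885 genes were higher and 2059 lower with ZFX12_13, 20.4% of those tested; the majority turned with GC and length offsets (2305 and 2092) and with upper-quartile factors (2021 and 1970).

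Against the shared empty-vector libraries, 2990 genes rose with both constructs where 937 were due by chance, and 2136 fell with both where 583 were due (1159 without replicate 2 and 1183 without replicate 3). SUSD2, WNT7B and NR5A1 rose with both, and CSRNP3 fell with both. Opposite changes numbered 38 and 43, where 775 and 704 were due. Across genes, which are not independent replicates, the changes correlated at r = 0.77 (Spearman 0.72), and 20 simulations of no effect gave r = 0.482. The covariance was 0.287 against a simulated 0.0178, at most 0.0186. Over the simulations at most 0 genes were called higher and 1 lower with both. These values argue against shared controls as the whole cause. Simulations of no effect cannot tell how much shared controls add where effects exist, so part of the shared excess may come from them. Of the 4488 genes higher with wtZFX, ZFX12_13 gave lower levels at 1545, MAFA and SUSD2 among them, and higher levels at 507. Of the 4045 higher with ZFX12_13, it gave higher levels than wtZFX at 1147, MAP6 and KCNK3 among them, and lower levels at 679, so each choice of genes favours its own construct.

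Setting siZFX in LN-229 beside wtZFX in DKO cells asked whether the same genes answered to ZFX in both lines, which share no libraries. All 10 leading falls with siZFX rose with wtZFX: DPYSL4 rose 3.71-fold (log2 1.89, SE 0.07, adjusted p = 8.8e-16), SMO by a log2 of 0.56 (SE 0.06) and CEP112 by 2.46 (SE 0.11). The other leading genes mirrored less. Of 10 leading rises with siZFX, 8 were tested with wtZFX, where 2 were lower and 1 higher. Of 10 leading rises with wtZFX, 5 were tested with siZFX, where 2 were lower and 0 higher. Of 10 leading falls with wtZFX, 4 were higher and 0 lower with siZFX. Chosen after the values were seen, DTX1, a Notch pathway gene, had log2 changes of -2.22 with siZFX and 3.13 with wtZFX, and the deacetylase gene HDAC11 had -2.61 and 1.99. Of 15973 genes tested in both lines 1397 were lower with siZFX and higher with wtZFX where 643 were due by chance (odds ratio 4.76, 95% interval 4.36 to 5.19, Fisher's exact test adjusted p = 2.6e-266). The 1397 are 49.2% of the 2841 genes lower with siZFX; without replicate 2 they numbered 843. Genes higher with siZFX and lower with wtZFX numbered 992 where 500.02 were due (odds ratio 3.42, adjusted p = 4.2e-139); 584 were found without replicate 1, 353 without replicate 2 and 1764 with GC and length offsets. Genes changed in the same direction numbered 280 higher with both (524 due) and 281 lower with both (614 due). Genes are not independent replicates, so these odds ratio intervals and Fisher p-values do not measure the spread between libraries. Across genes the changes correlated at r = -0.31 (Spearman -0.34). With siZNF593 in place of siZFX the lower and higher overlap was 701 where 546 were due (odds ratio 1.497), a test added after the data were examined.

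**Figure D4:**
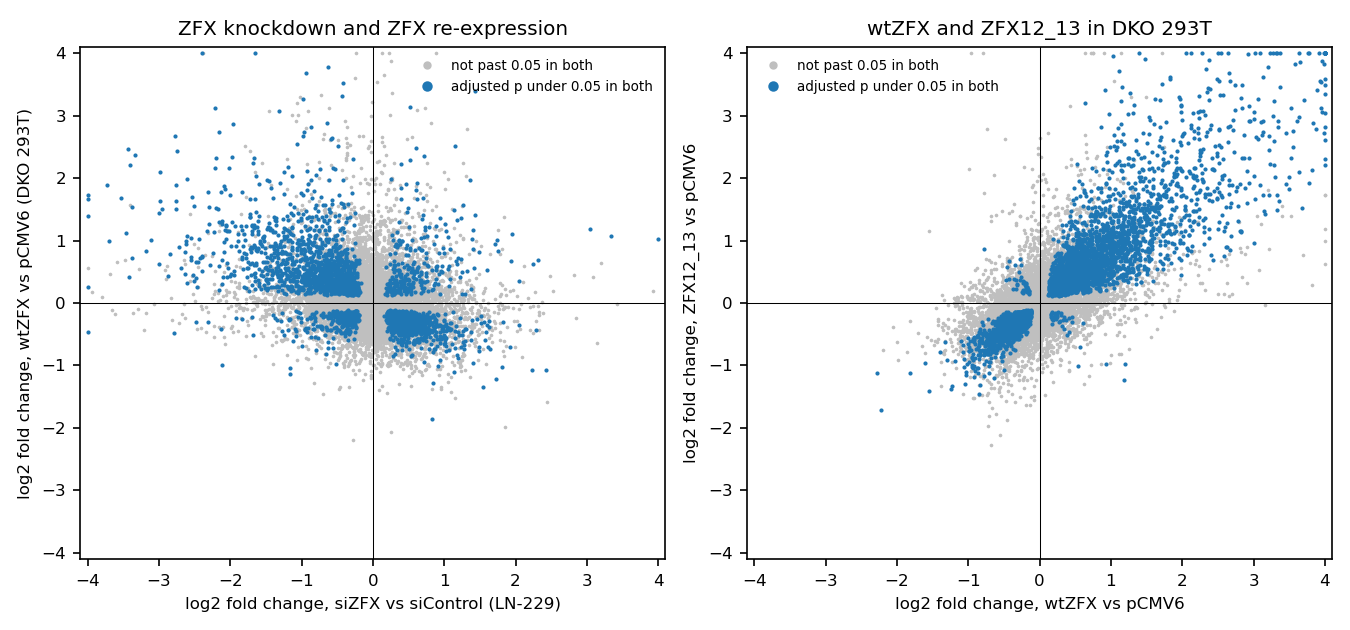
Each point is a gene, with log2 changes of siZFX and wtZFX on the left and of wtZFX and ZFX12_13 on the right, axes ending at 4 in either direction, and blue for genes past the test in both. The left panel slopes down (r = -0.31) and the right panel up (r = 0.77).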

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

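Chosen after the result was seen were the tests with siZNF593 in place of siZFX, of a weaker ZFX knockdown, of siZNF593 changes and of a raised level in siControl_2, and the rule that reads the intervals. All intervals in this section are taken over genes, which are not independent replicates. They do not measure the spread between libraries, and verdicts read from them carry that limit.

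Genes lower with siZFX in LN-229 were often higher with wtZFX in DKO cells (1397, odds ratio 4.76). Base composition could give such a pattern, but with GC and length offsets the odds ratio was 4.36 (95% interval 3.99 to 4.76), which argues against it. Expression level as the whole cause is argued against by 5 expression bins, the lowest of which gave 3.17 (2.63 to 3.81). Genes that answer to any siRNA would do the same with siZNF593 in place, where the odds ratio was 1.497, so this is not the whole cause. Other causes were not tested.

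The effects of the double knockdown and of siZFX differed at 3137 genes. Of these, 532 (17.0%, 15.7% to 18.3%) were also called between the control sets with the opposite sign. Genes not called there may differ too, and the calls rose from 961 and 863 to 1831 and 1869 with only the control sets fitted. That share therefore cannot limit the part due to the control sets. With siControl for both the controls cancel, and 2636 (84.0%) still differ in the same direction between double and siZFX libraries. Those genes were first chosen with the control libraries, and the direct comparison reuses the double and siZFX libraries that chose them. A high share was therefore likely beforehand, and it does not bear on a difference that siControl_2 and the double share. A weaker ZFX knockdown in the double (ZFX effects differing by 0.65) was put first to a test that gave 48.6% (1525, 46.9% to 50.4%) and did not decide. Its replacement, chosen after that value was seen, counted genes called in the double with a larger change than with siZFX. It gave 54.8% (1718, 53.004% to 56.5%). The genes were chosen by the same difference, and siControl_2 enters both, so that share cannot decide either. Changes from siZNF593 itself could account for 48.2% (1513, with 46.5% to 49.996%), which is undecided. Outside the sets of 532, 1525 and 1513 genes lay 526 others. In 100 splits of the libraries the real one, with 2998 genes in that fit, ranked 1 and the highest other gave 674. The splits mix libraries of groups that differ, which widens the spread within groups. That rank therefore cannot decide whether the effects differ.

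Inflammatory genes were lower with the double knockdown (median -1.23). Against siControl the median was -0.59 (-1.70 to -0.19 over the 24 genes) with 13 lower and 1 higher. A raised level in siControl_2 (0.66 above siControl) may therefore account for part and is undecided. The double library that lay apart is argued against as the cause, since without it the median was -1.20 with 21 of 24 lower and 1 higher. Its interval over the 24 genes ran from -1.90 to -0.78. With all 6 controls the median was -0.85, and the single knockdowns gave -0.11 and -0.27.

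Other differences between groups were large: 1000 genes away from the sum of single effects, 7164 between siZFX and siZNF593, 3944 between ZFX12_13 and wtZFX, and 11, 15 and 18 lists for the double against siZFX, the double against the sum, and siZFX against siZNF593. With an estimated correlation these were 0, 1 and 0 lists. For the sum 2 of 100 splits, the real one among them, gave as many genes as the real one or more, and the other gave 1487. These splits too mix groups that differ, so they cannot decide whether the effects depart from the sum. For comparisons of 3 with 3 libraries only 10 splits exist; the real one gave 7999 (siZFX), 6288 (siZNF593), 4762 (double), 3700 (control sets), 8483 (siZFX against siZNF593), 9602 (wtZFX), 6560 (ZFX12_13) and 3175 (ZFX12_13 against wtZFX), the highest other 0, which is too few splits to exclude chance.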

How the results depend on the processing

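The double library left out for lying apart, both stranded columns summed, offsets in overlaps, the motif test, and siControl in place of siControl_2 for list medians and for single genes in the differences were chosen after the result was seen. Of 394 gene counts under alternatives 39 moved more than 1.5-fold, of 14633 values of named genes 676 lost the call and 16 changed direction, and of 742 list tests 149 lost the call. The replicate block moved no count that far (2448 higher and 3035 lower with siZFX), and replicate numbers did not pair samples across groups (correlations -0.09 to 0.10 in LN-229, -0.05 to 0.04 in DKO cells). The cause was not tested for any change below; leaving out a library lowers power by construction, yet some counts rose without one.

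Counts of genes (main values in the report). With only the groups of the contrast: siZFX higher 3775, control sets 1831 and 1869. With GC and length offsets (and with the replicate block as well): siZFX higher 3704 (3681), siZNF593 lower 4130 (4106), control sets 1519 and 1447 (1488 and 1412), double minus siZFX lower 2947 (2946), minus the sum lower 708 (699), siZFX against siZNF593 higher 5520 (5494); with the block the share above the sum was 58.0% against 68.0%. Without the double library apart: control sets 1665 and 1838. With siControl in place of siControl_2: double minus siZFX 3006 and 3103 (controls cancel, so double against siZFX libraries), minus the sum 1607 and 1056. With all 6 controls: 2582 and 2710 (controls cancel again), 1689 and 1161. Leaving out 1 library: control sets higher 616 to 754 and lower 564 to 613; minus the sum 405 to 1334 above and 146 to 713 below.

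Overlaps. At 1.5-fold or more: siZFX with wtZFX 439 and 48, siZFX with siZNF593 148 and 159, wtZFX with ZFX12_13 1321 and 136. With GC and length offsets: higher with siZFX and lower with wtZFX 1764. Leaving out 1 replicate number in every group: siZFX with siZNF593 178 to 506 and 327 to 1013, siZFX with wtZFX 843 to 1250 and 353 to 662, wtZFX with ZFX12_13 lower 1159 to 1932.

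Lists past the test. With an estimated correlation: siZFX 0, siZNF593 2, double 1, control sets 4, double minus siZFX 0, minus the sum 1, siZFX against siZNF593 0, wtZFX 0, ZFX12_13 0. With fry, which tests against no change: siZFX 17, double 21, wtZFX 16, ZFX12_13 16, ZFX12_13 against wtZFX 3. Leaving out 1 replicate number in every group: siZFX 5 to 9, double minus siZFX 7 to 12, wtZFX 5 to 10, ZFX12_13 3 to 7, ZFX12_13 against wtZFX 0 to 9.

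Named genes that changed direction. Double with siControl in place: CALB2 -1.21, C3 0.51, ELL2 -0.0612, MT-CO2 0.16, FABP7 0.65, MAP2 0.14. With all 6 controls: CALB2 -0.41, FABP7 0.0117 (double), CKB -0.11 (siZFX) and -0.0532 (siZNF593), MT-CO1 -0.0280 and LRP2 -0.34 (siZNF593). With GC and length offsets, without and then with the block: BOP1 -0.0799 and -0.0798 (wtZFX), CHAC1 -0.0370 and -0.0351 (ZFX12_13). Motif odds ratio, siZFX higher, AGGCCTAG only: 1.10.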

Other observations

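Both motif tests were chosen after the result was seen, as the genes below were.

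Some genes moved in a way the comparisons above leave out. LRATD2 fell with siZNF593 from 193 ± 2.81 to 25.9 ± 3.13 CPM, and the zinc and iron transporter gene SLC39A14 from 157 ± 11.1 to 24.4 ± 3.06 CPM (log2 -2.69, SE 0.09), beside the fall of TFRC. The glial fatty acid binding protein gene FABP7 fell with siZFX from 62.0 ± 4.79 to 15.1 ± 0.656 CPM, and IRF7, an interferon regulatory factor gene, rose from 8.12 ± 1.16 to 21.4 ± 1.61 CPM. In DKO cells the oligodendrocyte gene OLIG1 rose with wtZFX from 2.87 ± 0.497 to 12.3 ± 0.227 CPM and CSPG4 from 12.7 ± 0.647 to 29.9 ± 1.29 CPM, opposite to their falls with siZFX in LN-229 (log2 -2.98 and -2.06).

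NEXMIF, a gene of neurite development, rose with wtZFX by a log2 of 2.63 and not with ZFX12_13 (0.31, adjusted p = 0.16), as NGFR did. CHRDL2, a bone morphogenetic protein antagonist gene, stood at 10.1 ± 0.727 CPM with ZFX12_13 and 1.59 ± 0.640 CPM with wtZFX. With ZFX12_13 the co-chaperone gene BAG3 rose from 42.8 ± 0.951 to 73.8 ± 3.84 CPM.

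The sequence AGGCCTRG was sought in the first 300 transcribed bases of protein-coding genes, of which 7971 of 19659 (40.5%) had a sequence to read, and 341 of those held it. Fewer than 80% of genes have a value, and the promoter itself was not read, so this check is void as a test of ZFX binding. Genes lower with siZFX held it with an odds ratio of 1.10 (0.811 to 1.501, adjusted p = 0.718) and genes higher with wtZFX with 1.09 (0.828 to 1.42, adjusted p = 0.718). Of 10 tests 1 passed: among genes lower with ZFX12_13, 22 of 980 held it against 230 of 4940 others (odds ratio 0.470, adjusted p = 0.00354).

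The unstranded column leaves out reads that meet more than one gene. At 1 CPM or more, 280 of 12434 protein-coding genes in LN-229 and 227 of 13754 in DKO cells kept under 1 in 10 of their reads, and 33 and 30 kept none, ZNF593 among them.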
